A study of Mus musculus with 13 samples.

How the data were processed

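The series holds 13 mRNA sequencing libraries from mouse bone marrow cells. Wild-type granulocyte-monocyte progenitors (GMP), MLL-AF10 leukemia stem cells (LSC) and mature leukemia cells (mAML) had 1 library each. LSC treated with A-485, an inhibitor of the acetyltransferase activity of p300 and CBP, had 2 libraries at each of 5 times: 0, 8, 24, 48 and 72 h. Per the labels the 0 h libraries were untreated, there was no vehicle control for the later times, and the dose was not given in the sources used here. The 2 libraries of a time are not said to come from separate cultures, so the p-values may measure technical spread.

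Per the submitters' processing notes, the authors used STAR and RSEM with the mouse build mm9; the versions and settings were not given in the sources used here. Per the file headers, each deposited file gives an expected count and a transcript abundance (TPM) for each of 24328 genes. The deposited expected counts are estimated reads per gene and are not scaled to library size. The deposited TPM are scaled for length and depth within each library. Because the build is older than the annotation at hand, no coordinates are given.

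Expected counts were rounded to whole numbers. The total was 24532500 counts in GMP, 40468500 in LSC and 47257600 in mAML, and ranged from 6467760 to 9763280 in the time course. For the time course, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, filterByExpr (11119 genes tested) and the quasi-likelihood test, with time as a factor, no replicate block and all 10 libraries in 1 model. Each treated time was compared with 0 h, 72 h was compared with 8 h, and all 4 treated times were tested together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are given with an approximate standard error, the absolute log2 change divided by the square root of the F value of the test. Levels are TMM-scaled counts relative to library size (CPM) with their SD, n = 2 libraries per time, except where said. The common biological coefficient of variation was 0.186. In simulated data with 10945 genes, 100 genes changed 2-fold and 100 changed 4-fold at each treated time. The test recovered 39% to 52% of 2-fold and 82% to 84% of 4-fold changes against 0 h. False calls were 8 of 131, 9 of 145, 6 of 142 and 12 of 138 calls at 8, 24, 48 and 72 h. Far more genes were called in the real data, so these rates need not hold there.

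The single libraries have no replicates and no test. They were compared by the log2 ratio of TMM-scaled CPM with a prior count of 5, with the 95% exact binomial interval of the 2 counts, and genes with at least 10 CPM in the higher library and at least a 4-fold difference were counted. Where a group had 0 counts, a fold is given as at least the value from a floor of 3 counts over the group. Intervals and floors cover counting error only.

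The 29 gene lists, the genes to be named, the tests and the other settings to try were set before the data were examined. The lists were MLL-fusion targets, stem and progenitor genes, hematopoietic transcription factors, MYC targets, ribosomal protein genes, S-phase genes, G2/M genes, p53 targets, BCL2-family genes, primary granule genes, neutrophil maturation genes, monocyte and macrophage genes, antigen-presentation and dendritic genes, interferon response genes, immediate-early genes, cholesterol synthesis genes, ATF4 and unfolded protein response genes, hypoxia and glycolysis genes, oxidative phosphorylation genes, lysosome genes, acetyltransferases and acetyl-lysine readers, histone deacetylases and sirtuins, and genes of the MLL-fusion complexes and of histone methylation. There were also markers of erythroid, megakaryocyte, B, T and NK cells, of mast cells, basophils and eosinophils, and of stromal and endothelial cells. Called genes were counted per list, over all genes tested and adjusted over the list alone. Lists with at least 5 measured genes were tested with camera in limma 3.58.1, with the inter-gene correlation estimated from the data and Benjamini-Hochberg adjustment over lists and times. In the single libraries, a list median was placed among 10000 random lists of the same size matched on expression, and list genes at least 2-fold apart were counted. The random lists draw genes independently, so a list whose genes vary together reaches an extreme percentile more readily. A percentile is therefore not a test. Sets of genes at least 4-fold different between LSC and GMP or between LSC and mAML were tested in the time course with camera, as the lists were.

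The genes named are 28 genes fixed in advance, with Ep300 and Crebbp first, and genes picked by rank. At 8 and 72 h these were the 8 largest rises and 8 largest falls, at 24 and 48 h the 4 and 4, and for 72 h against 8 h the 6 and 6. The gene had to be called, to reach 10 CPM in the higher group, and to have both libraries of one time beyond both of the other. Each list gave up to 4 members with the smallest adjusted p. In the single libraries the 12 largest ratios in each direction and up to 4 members of each list were eligible, with at least 20 CPM in the higher library. Unnamed loci, Y-linked genes and Xist were not named.

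The alternatives were DESeq2 1.42.0 size factors and the DESeq2 test, library size alone, no low-count filter, a filter of at least 5 CPM in at least 2 libraries, the replicate number as a block, limma on log2 of the deposited TPM plus 1, only the 4 libraries compared, and leaving out each library in turn. For lists they were a preset correlation of 0.01 and fry. For the single libraries they were the deposited TPM with 1 added, library size alone, a prior count of 1, and a minimum of 1 or 50 CPM. The sets were also built at 8-fold. Leaving out the ribosomal RNA gene Rn45s, leaving out 3 libraries, and removing the trend on transcript length were chosen after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots. Effective lengths and FPKM were not used here.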

Results

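Mouse leukemia driven by the fusion gene MLL-AF10 was profiled to ask how its stem cells differ from normal progenitors and from more mature leukemia cells. The stem cells were also followed under an inhibitor of p300 and CBP, enzymes that acetylate histones at enhancers. The 3 single libraries are given first, without a test, and brackets there hold the 95% exact counting interval. Percentiles of lists there do not allow for genes of a list varying together.

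Hoxa9, a homeobox gene that MLL fusions keep active, was at 179 CPM in LSC and 13.5 CPM in GMP, a log2 ratio of 3.72 [3.58, 3.89]. Its cofactor genes Meis1 and Pbx3 had ratios of 3.68 [3.49, 3.92] and 4.43 [4.17, 4.83], and Hoxa5 had 5.93 [5.60, 6.53]. Hoxa10 was at 63.9 CPM in LSC and had 2 counts in GMP (0.0754 CPM). Mecom, which encodes a stem cell transcription factor, had a ratio of 4.89 [4.47, 5.94], and Eya1 had 4.58 [4.35, 4.92]. The MLL-fusion targets had a median of 1.45 over 24 genes, at percentile 100 of matched random lists, with 13 genes at least 2-fold higher and 4 lower. Under TPM with 1 added that median was 0.66. In all, 353 genes were at least 4-fold higher and 264 at least 4-fold lower in LSC than in GMP, of 9018 considered. The genes encoding the drug targets differed less: Ep300 had a ratio of 0.37 [0.30, 0.43] and Crebbp 0.38 [0.25, 0.51].

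Several surface and fate genes of progenitors did not move together between LSC and GMP. Kit, the receptor for stem cell factor, was at 331 CPM in LSC and 337 CPM in GMP, a log2 ratio of -0.03 [-0.06, 0.01]. Cd34 was lower (-2.44 [-2.50, -2.38]), as were Flt3 (-2.23 [-2.76, -1.90]) and Bcl2 (-2.73 [-2.90, -2.59]). Irf8, which directs monocyte and dendritic fate, was at 20.7 CPM in LSC and 328 CPM in GMP (-3.98 [-4.09, -3.89]), while Gfi1, which directs neutrophil fate, was higher (1.57 [1.52, 1.62]). Spi1 had a ratio of 1.03 [0.98, 1.08] and the integrin gene Itgam 3.64 [3.57, 3.72]. The stem and progenitor genes had a median of -0.51 over 19 genes (percentile 0.82), with 4 genes at least 2-fold higher and 9 lower. The hematopoietic transcription factors had a median of 0.57 over 30 genes (percentile 99.98; 12 higher, 2 lower).

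Neutrophil genes of late granules were among those that differed most between LSC and GMP. Chil1 was at 928 CPM against 0.452 CPM in GMP (10.63 [10.20, 11.96]), and Olfm4 (9.65 [9.26, 10.60]), Chil3 (9.20 [9.08, 9.33]) and Camp (7.84 [7.62, 8.16]) were higher as well. Hpgd, a prostaglandin-degrading enzyme gene, had a ratio of 10.52 [10.13, 11.50]. Ptprt was at least 802-fold higher and Slc13a5 at least 219-fold higher, each with 0 counts in GMP. Stfa1 was also higher (9.14), but reads are shared within its gene family, so its level is uncertain. The neutrophil maturation genes had a median of 3.83 over 22 genes (percentile 100; 17 at least 2-fold higher, 1 lower), against -0.19 for 15 primary granule genes (percentile 6.11; 3 higher, 5 lower). Mpo, the primary granule enzyme, was at 11374 CPM in LSC and 22748 CPM in GMP, while Elane had a ratio of 0.51 [0.50, 0.52]. The monocyte and macrophage genes had a median of 0.60 over 36 genes (percentile 99.9; 15 higher, 7 lower), or 0.24 under TPM with 1 added.

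Most eosinophil, mast cell and erythroid markers were lower in LSC than in GMP. Epx was at 0.0249 CPM in LSC, from 1 count, and 165 CPM in GMP. Prg2 was at 2.39 CPM and 437 CPM (-7.43 [-7.82, -7.22]), Maoa was at least 394-fold lower, and Cpa3 had a ratio of -4.89 [-5.54, -4.61]. The mast-cell, basophil and eosinophil markers had a median of -3.12 over 11 genes (percentile 0; 1 higher, 9 lower), and the erythroid markers -3.08 over 11 (percentile 0.93; 1 higher, 10 lower). Under TPM with 1 added these medians were -2.43 and -1.15. The megakaryocyte markers had a median of -0.62 (percentile 34.5).

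MYC target, S-phase and respiration lists had medians below 0 in LSC against GMP, and mitotic and immediate-early lists above 0. The MYC targets had a median of -0.74 over 50 genes (percentile 0; 0 at least 2-fold higher, 14 lower), with Pus7 at -1.998 [-2.12, -1.89] and Cad at -1.71 [-1.77, -1.65], and Myc itself had a ratio of -0.56 [-0.61, -0.51]. The S-phase genes had a median of -0.51 over 45 genes (percentile 0), the oxidative phosphorylation genes -0.45 over 44 (percentile 0), and the ATF4 and unfolded protein response genes -0.47 (percentile 0.03). The G2/M genes had a median of 0.64 over 50 (percentile 100), with Cdc25b at 1.67 [1.55, 1.80] and Ube2c at 1.28 [1.22, 1.34]. The immediate-early genes had a median of 2.001 over 26 genes (percentile 100; 19 higher, 5 lower), led by Egr1 (5.12 [4.70, 6.27]) and Dusp1 (4.57 [4.41, 4.76]). Medians for the lysosome (0.46), cholesterol synthesis (0.41), hypoxia and glycolysis (0.36), p53 target (0.42) and BCL2-family (0.40) lists were at percentiles 99.9, 99.04, 98.7, 97.3 and 93.4. The antigen-presentation and interferon lists had medians of -0.25 (percentile 12.1) and -0.22 (percentile 15.8), and the stromal markers 0.29 (percentile 73.6). The ribosomal, acetyltransferase, deacetylase and MLL-complex lists had medians of 0.18, 0.08, 0.08 and 0.00. Under library size alone the last 3 turned negative, and all 4 did under TPM. These scalings moved the median of all genes by -0.13 and -0.23.

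Most monocyte, macrophage and antigen-presentation genes were higher in mAML than in LSC. Fn1, encoding fibronectin, was at 4229 CPM in mAML and 4.79 CPM in LSC (9.75 [9.58, 9.999]), and S100a4 (9.27 [8.99, 10.40]), Cd163 (9.21 [9.01, 11.58]) and Nlrp3 (8.37 [8.17, 10.74]) were higher too. Irf8 was at 743 CPM against 20.7 CPM (5.16 [5.07, 5.27]), and the monocyte factor gene Klf4 (6.64 [6.43, 7.01]), the receptor gene Csf1r (3.06 [3.01, 3.11]) and Lyz2 (3.61 [3.60, 3.63]) were higher. The monocyte and macrophage genes had a median of 2.28 over 38 genes (percentile 100; 27 at least 2-fold higher, 3 lower), and the antigen-presentation and dendritic genes 2.997 over 22 (percentile 100; 15 higher, 0 lower), with Cd74 at 4.65 [4.50, 4.86]. The neutrophil maturation list was also higher, at 2.55 over 24 genes (percentile 100; 18 higher, 1 lower), with Retnlg at 8.17 [7.90, 8.91] and Mmp8 at 8.07 [7.88, 8.39]. Markers of other cell types were higher in the same library: Cd22, a B-cell gene, was at 23.1 CPM against 0.274, Thy1 at 34.1 CPM, and Ccl5 at 36.7 CPM against 0.349. Of 14 B-cell markers 4, and of 18 erythroid markers 8, reached 1 CPM in mAML or LSC. The 4 B-cell genes were too few for a list median. T- and NK-cell markers had a median of 5.43 over 18 genes, or 5.57 with genes at 0 set to their bound (percentile 100; 18 higher, 0 lower), and erythroid markers 7.63 over 8 (percentile 100), in which globin reads are shared between paralogs and are uncertain. Under TPM with 1 added the T- and NK-cell, erythroid and antigen-presentation medians were 2.92, 5.70 and 1.63.

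Most primary granule genes were lower in mAML than in LSC. Mpo was at 71.7 CPM against 11374 CPM (-7.31 [-7.36, -7.26]) and Kit at 2.34 CPM against 331 CPM (-7.07 [-7.44, -6.87]). Ms4a3 (-6.14 [-6.29, -6.03]), Prss57 (-4.53 [-4.71, -4.41]), Elane (-4.23 [-4.26, -4.21]) and Gfi1 (-4.29 [-4.41, -4.20]) were also lower, and the primary granule genes had a median of -2.47 over 15 genes (percentile 0; 0 higher, 12 lower). Hoxa9 (-0.64 [-0.70, -0.59]), Meis1 (-0.56 [-0.63, -0.49]) and Pbx3 (-0.13 [-0.20, -0.05]) differed less, and the MLL-fusion targets had a median of -0.42 over 23 genes (percentile 0.29; 4 higher, 2 lower). Myc (-2.12 [-2.21, -2.05]), Myb (-1.37 [-1.41, -1.34]) and Mki67 (-1.18 [-1.21, -1.16]) were lower, while Bcl2 (2.13 [1.99, 2.30]), Cd34 (1.89 [1.83, 1.96]) and Cdkn1a (2.70 [2.52, 2.97]) were higher. The G2/M genes had a median of -1.22 over 50 genes (percentile 0; 0 higher, 39 lower), with Ube2c at -1.97 [-2.03, -1.91] and Aurka at -1.71 [-1.78, -1.64]. Ep300 and Crebbp had ratios of 0.57 [0.52, 0.62] and 0.70 [0.61, 0.80]. In all, 563 genes were at least 4-fold higher and 127 at least 4-fold lower in mAML than in LSC, of 9135 considered.

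The remaining lists between mAML and LSC went both ways. The interferon response genes had a median of 1.51 over 34 genes (percentile 100; 21 higher, 1 lower) and the immediate-early genes 1.46 over 28 (percentile 100; 18 higher, 1 lower), with Irf7 at 4.11 [3.89, 4.48] and Fosl2 at 3.99 [3.89, 4.13]. BCL2-family (0.85), p53 target (0.76), lysosome (0.54), hematopoietic transcription factor (0.43) and stromal (2.07) lists had percentiles of 99.96, 99.96, 99.99, 99.9 and 98.3. Lower medians were those of the stem and progenitor (-0.58, percentile 0.18), MYC target (-0.48, percentile 0), ribosomal (-0.43, percentile 0.03) and S-phase (-0.40, percentile 0.02) lists. The mast-cell list had -0.20, the deacetylase list -0.19, the oxidative phosphorylation list -0.06 and the ATF4 list -0.01. The cholesterol list had 0.19 (percentile 95.9). The MLL-complex (0.08), hypoxia (0.05) and acetyltransferase (0.04) lists turned negative under library size alone, which moved the median of all genes by -0.09, and the last 2 of them under TPM as well.

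mAML cells differed from GMP in MLL-fusion targets, in mature myeloid genes and in markers of other cell types. Hoxa9 (3.08 [2.93, 3.25]), Meis1 (3.12 [2.92, 3.36]) and Pbx3 (4.31 [4.05, 4.70]) were higher, and the MLL-fusion targets had a median of 1.95 (percentile 100; 14 higher, 4 lower). Thbs1 (10.10 [9.69, 11.19]), Hpgd (10.90 [10.51, 11.88]), Olfm4 (10.81 [10.42, 11.76]) and Ltf (8.61 [8.42, 8.86]) were higher, and Mpo (-8.31 [-8.36, -8.26]), Kit (-7.09 [-7.47, -6.89]) and Prg2 (-7.33 [-7.68, -7.13]) lower. The neutrophil maturation genes had a median of 7.37 over 24 (percentile 100; 23 higher, 0 lower), the monocyte and macrophage genes 3.59 over 35 (29 higher, 1 lower) and the immediate-early genes 3.58 (24 higher, 3 lower). In the same library the T- and NK-cell markers had a median of 5.10 over 18 genes, or 5.205 with genes at 0 set to their bound (percentile 100; 18 higher, 0 lower). The stromal markers had 3.35 over 9 (percentile 99.4; 6 higher, 2 lower). Under TPM with 1 added the stromal median was 1.34 and that of the T- and NK-cell markers 2.93. The MYC targets had -1.20 (0 higher, 34 lower), the S-phase genes -0.92 (0 higher, 16 lower) and the primary granule genes -3.01 (2 higher, 13 lower), each at percentile 0. In all, 843 genes were at least 4-fold higher and 263 at least 4-fold lower, of 9300 considered.

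**Figure D1:**
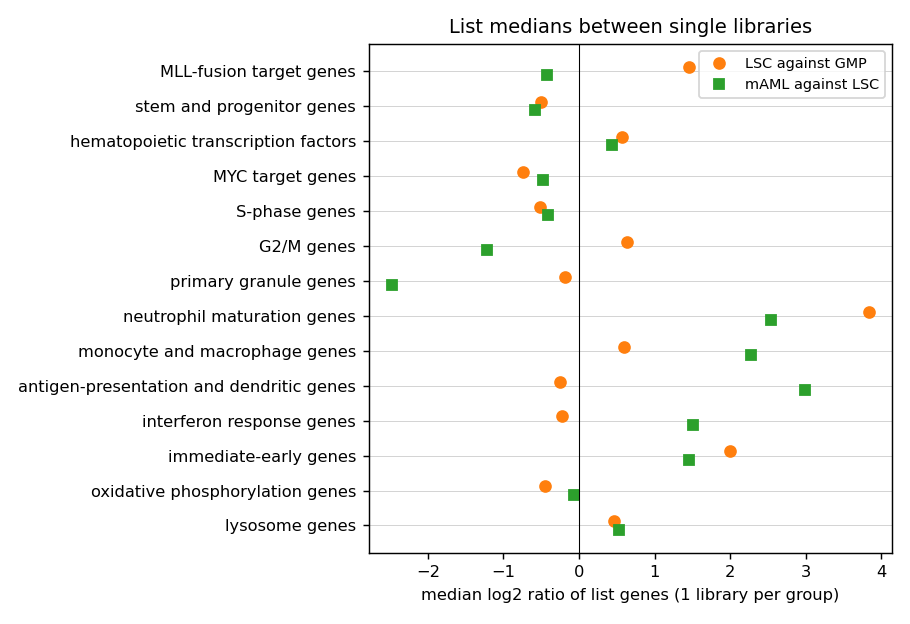
Median log2 ratio of the genes of 14 lists between single libraries, LSC against GMP and mAML against LSC. There are no replicates, and none of the medians drawn changes sign under library size or TPM scaling. Their sizes do change. Under TPM with 1 added, the MLL-fusion target median for LSC against GMP went from 1.45 to 0.66. The antigen-presentation median for mAML against LSC went from 2.997 to 1.63. Other medians grew, such as that of the MYC targets for LSC against GMP, from -0.74 to -0.95.

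In the A-485 time course, the genes encoding the drug targets were higher at every treated time. Ep300 rose from 155 ± 10.5 CPM at 0 h to 361 ± 25.01 CPM at 8 h, a log2 change of 1.22 ± 0.14 (adjusted p = 0.000342, n = 2), and Crebbp rose from 45.7 ± 2.24 to 146 ± 18.5 CPM (1.67 ± 0.13, adjusted p = 6.23e-05). At 72 h the changes were 1.71 ± 0.14 (adjusted p = 3.06e-05) and 1.89 ± 0.13 (adjusted p = 1.58e-05). Both treated libraries lay above both 0 h libraries at each time, and from 8 to 72 h Ep300 rose by a further 0.49 ± 0.13 (adjusted p = 0.0239) while Crebbp did not pass the test (0.22 ± 0.12, adjusted p = 0.205). That further rise of Ep300 did not hold without 72 h replicate 1 (0.39, adjusted p = 0.125) or 8 h replicate 1 (0.41, 0.119), or with the trend on transcript length removed (0.22, 0.114). The libraries also changed in make-up with time: the mean transcript length per read was 3124 and 3110 nt at 0 h and 3775 and 3656 nt at 72 h. The nuclear RNAs Malat1 and Neat1 were chosen after their values were seen, and their CPM here are without TMM scaling. Malat1 went from 266 and 272 CPM at 0 h to 2853 and 3276 CPM at 72 h. Neat1 went from 95.5 and 104 CPM to 898 and 2326 CPM. The TMM factors were 0.830 and 0.832 at 0 h and 1.07 in both 72 h libraries, so with TMM scaling these rises would be smaller. With the trend on transcript length removed, Ep300 and Crebbp stayed called higher against 0 h in 8 of 8 tests.

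Kit and Myc had fallen by 8 h of A-485. Kit fell from 201 ± 1.9998 to 7.05 ± 1.58 CPM (-4.83 ± 0.36, adjusted p = 5.39e-05) and Myc from 472 ± 35.1 to 19.6 ± 11.7 CPM (-4.59 ± 0.68, adjusted p = 0.00124). Cebpa (-2.51 ± 0.13), Runx1 (-2.09 ± 0.25), Cd34 (-2.04 ± 0.12), Myb (-1.82 ± 0.21), Gfi1 (-1.56 ± 0.15) and Bcl2 (-0.996 ± 0.15) fell, all with adjusted p from 1.67e-05 to 0.00145 by edgeR's quasi-likelihood test. The Bcl2 call was lost with limma on log2(TPM + 1) (-0.45, adjusted p = 0.0514). Hoxa9 was at 132 ± 27.4 CPM against 140.0 ± 20.6 CPM (-0.08 ± 0.22, adjusted p = 0.803) and Hoxa10 and Meis1 did not pass the test either (-0.05 ± 0.47 and 0.49 ± 0.33, adjusted p = 0.942 and 0.267), whereas Pbx3 rose (1.07 ± 0.14, adjusted p = 0.000665). The Hoxa9 and Hoxa10 changes at 8 h were positive under library size and TPM scaling, still without a call. In all, 1987 genes were called higher and 2337 lower at 8 h, of 11119 tested. These were 4078 and 1520 under library size alone, so the balance depends on scaling. Without 8 h replicate 2 they were 1186 and 1613.

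The largest rises at 8 h were in interferon-induced genes and a few others. Ifit1 was at least 80.4-fold higher (15.8 CPM against 0 counts at 0 h, adjusted p = 0.00946), and Usp18 (5.02 ± 1.13), Gbp2 (4.30 ± 0.45), Irf7 (3.56 ± 0.42), Rsad2 (3.25 ± 0.92) and Cxcl10 (3.53 ± 1.22, adjusted p = 0.0478) rose, as did Gatsl2 (4.56 ± 0.42) and Wdr47 (3.68 ± 0.27). Without 8 h replicate 2, Cxcl10 had a change of 1.22 (adjusted p = 0.525) and Rsad2 3.24 (adjusted p = 0.0590). Of 30 measured interferon response genes, 14 rose and 1 fell at 8 h (16 and 1 adjusted over the list alone), with a median of 2.26 and a list adjusted p = 0.417 with an estimated correlation. Ddx58 rose by 2.08 ± 0.16. At 24, 48 and 72 h the list counts were 12, 17 and 8 higher and 2, 1 and 2 lower (11, 17 and 7 higher and 2, 1 and 1 lower adjusted over the list alone), with medians of 1.26, 1.27 and 0.94, or 1.06 and 0.86 at 24 and 72 h with genes at 0 set to their bound. The adjusted p was 0.490, 0.490 and 0.585 with an estimated correlation.

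The largest falls at 8 h, picked by rank, included genes of adhesion, coagulation and glucose transport, themes that had no list of their own. Thbs1 fell from 5866 ± 165 to 58.1 ± 41.6 CPM (-6.66 ± 0.83, adjusted p = 0.000587), F13a1 fell by the same test (-6.81 ± 0.62, adjusted p = 0.000131), and so did Cldn15 (-6.88 ± 0.51), Slc2a3 (-6.76 ± 0.88), Itgb3 (-6.20 ± 1.09), Clec4b2 (-6.19 ± 1.19) and Lipg (-6.15 ± 0.80). Cd28 was at 0.0575 CPM, from 1 count, against 12.5 CPM at 0 h. Slc2a3 belongs with a wider group: all 30 measured hypoxia and glycolysis genes fell at 8 h (30 adjusted over the list alone), with a median of -2.07 and adjusted p = 0.274 with an estimated correlation. Bnip3 went from 1087 ± 53.8 to 82.2 ± 7.41 CPM (-3.72 ± 0.14, adjusted p = 6.69e-06), and Eno1 (-2.42 ± 0.10), Tpi1 (-2.22 ± 0.10) and Gpi1 (-2.07 ± 0.09) fell. At 24, 48 and 72 h 26, 25 and 27 of them were lower (26, 27 and 27 adjusted over the list alone), with medians of -1.73, -1.72 and -1.81 and adjusted p = 0.274 at each time with an estimated correlation. The 0 h libraries had this list higher than the single LSC library did, by a median of 1.74, in 29 of 30 genes.

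Mpo, the main enzyme of primary granules, was at 2714 CPM at 0 h and at 351 and 27.1 CPM in the 8 h libraries (-3.84 ± 0.96, adjusted p = 0.0163), a call that did not hold without 0 h replicate 1 (-3.58, adjusted p = 0.0607) or with the DESeq2 test (-3.85, adjusted p = 0.110). At 72 h it had 0 counts, at least 14787-fold lower (adjusted p = 0.000415). Elane (-7.77 ± 1.59, adjusted p = 0.00339), Ctsg (-10.48 ± 0.52, adjusted p = 4.95e-06) and Ms4a3 (-10.26 ± 0.47) fell as well by 72 h. All 14 measured primary granule genes were lower at each of the 4 times (14 adjusted over the list alone), with medians of -3.57, -4.88, -5.52 and -6.02 and adjusted p = 0.274 with an estimated correlation. The 8 h library with the lower Mpo also had Wnt2 at 67.1 CPM, Susd5 at 65.6 CPM and Foxc1 at 223 CPM, genes chosen after their values were seen that stood at up to 3.58, 2.51 and 42.3 CPM in the 7 libraries without this feature. Of 16 neutrophil maturation genes, 8, 12, 13 and 14 fell at 8, 24, 48 and 72 h (10, 13, 13 and 15 adjusted over the list alone) and 0 rose, with medians of -2.10, -3.94, -4.42 and -6.36, the last -5.68 with genes at 0 set to their bound. Their adjusted p was 0.377, 0.470, 0.490 and 0.452 with an estimated correlation.

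Most G2/M and S-phase genes were called lower from 24 h on, and calls at 8 h depended on scaling. Mki67, which marks cycling cells, did not pass the test at 8 or 24 h (0.42 ± 0.48 and -1.31 ± 0.49, adjusted p = 0.518 and 0.0525). It was at 18.99 ± 14.8 CPM at 48 h and 4.38 ± 1.76 CPM at 72 h against 715 ± 16.4 CPM at 0 h, changes of -5.24 ± 0.60 (adjusted p = 0.000155) and -7.34 ± 0.69 (adjusted p = 5.74e-05). Of 50 G2/M genes, 2 rose and 2 fell at 8 h (0 and 0 adjusted over the list alone), and 41, 50 and 50 fell at 24, 48 and 72 h (44, 50 and 50 adjusted over the list alone), with medians of 0.41, -1.49, -4.63 and -5.06 and adjusted p = 0.667, 0.377, 0.346 and 0.346 with an estimated correlation. Aurkb (-7.60 ± 0.52) and Top2a (-4.69 ± 0.34) fell, and Ccnb2 was at least 772-fold lower at 72 h. Of 45 S-phase genes, 11 fell at 8 h (8 adjusted over the list alone) and 44 at each later time (44 adjusted over the list alone), with medians of -0.25, -2.04, -3.07 and -2.91 and adjusted p = 0.606 and then 0.274 at each later time with an estimated correlation. Cdc45 fell at 48 h (-5.11 ± 0.20) and Rrm2 at 72 h (-6.34 ± 0.33). The S-phase median at 8 h was positive under library size and TPM scaling, at 0.06 and 0.19. Of the G2/M genes 12 and 14 were called higher at 8 h and 0 lower under these scalings.

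Most MYC targets and cholesterol synthesis genes were called lower at all 4 treated times, and ribosomal protein genes depended on scaling at 8 and 24 h. Of 50 MYC targets, 37, 47, 47 and 44 fell at 8, 24, 48 and 72 h (38, 47, 47 and 45 adjusted over the list alone) and 0 rose, with medians of -0.82, -1.50, -1.60 and -1.34 and adjusted p = 0.274 with an estimated correlation. Srm (-2.38 ± 0.18) and Pa2g4 (-1.16 ± 0.08) fell at 8 h, and Cdk4 at 72 h (-2.01 ± 0.09, adjusted p = 3.73e-06). Of 40 ribosomal protein genes, 34, 37, 39 and 39 fell (36, 38, 40 and 39 adjusted over the list alone), with medians of -0.55, -0.67, -1.22 and -1.23 and adjusted p = 0.327, 0.327, 0.290 and 0.290 with an estimated correlation. Under library size alone 9, 21, 37 and 36 of them fell, and with the trend on transcript length removed 25, 18, 29 and 33. Rpsa went from 4446 ± 26.6 to 1009.8 ± 17.04 CPM at 72 h (-2.14 ± 0.10). Of 22 cholesterol synthesis genes, 16, 21, 21 and 21 fell and 1 rose at 8 h (18, 21, 21 and 21 and 1 adjusted over the list alone), with medians of -1.18, -1.96, -2.06 and -2.01 and adjusted p = 0.330, 0.320, 0.321 and 0.321 with an estimated correlation. Insig1 fell at 8 h (-2.39 ± 0.18).

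**Figure D2:**
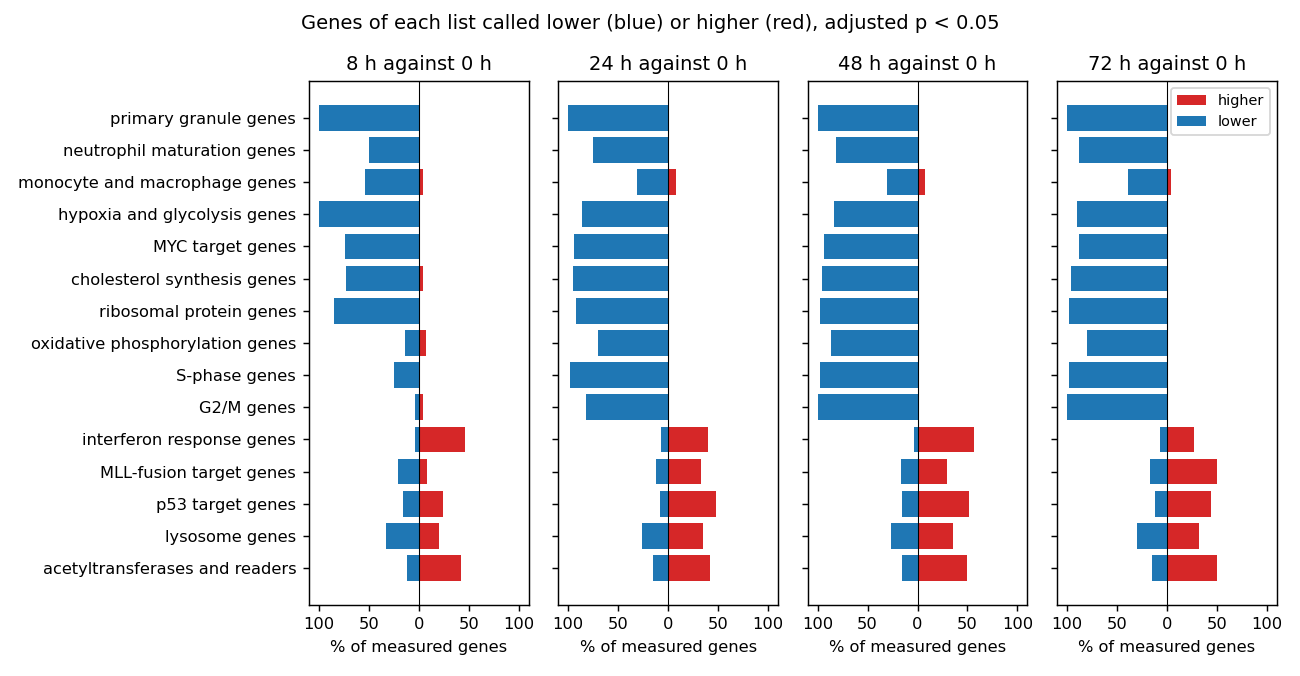
Share of the measured genes of 15 lists called lower (left, blue) or higher (right, red) at each time against 0 h, adjusted p under 0.05, 2 libraries per time. Under library size or TPM scaling, the majority at 8 h turns to higher for the S-phase, oxidative phosphorylation, lysosome and MLL-fusion target lists, and the G2/M list gains higher calls.

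At 24 h 2584 genes were called higher and 3011 lower, or 4175 and 2012 under library size alone. Mpo was at 0.270 CPM against 2714 CPM at 0 h (-13.15 ± 1.67, adjusted p = 0.000618), Pde11a was at least 69.3-fold lower and Lipg fell (-9.47 ± 1.04). Camp was at least 64.4-fold lower (adjusted p = 0.0263), a call that did not hold with the DESeq2 test (adjusted p = 0.0624) or without 0 h replicate 1 (0.124), 24 h replicate 1 (0.0680) or 24 h replicate 2 (0.0712). Pcdhgb7 was at least 56.8-fold higher, and Gbp2 (5.32 ± 0.45, adjusted p = 6.24e-05) and Gatsl2 (5.32 ± 0.42) rose. L1cam was at 13.4 CPM against 0.185 CPM, from 3 counts at 0 h. Kit was at 1.72 ± 1.09 CPM (-6.84 ± 0.41) and Myc at 10.3 ± 7.48 CPM (-5.51 ± 0.72, adjusted p = 0.000458). Meis1 (0.97 ± 0.33, adjusted p = 0.0381) and Spi1 (0.72 ± 0.19, adjusted p = 0.0131) rose, but Meis1 was at 0.49 (adjusted p = 0.266) without 24 h replicate 2 and 0.71 (adjusted p = 0.197) without 0 h replicate 1. Spi1 was not called without 0 h replicate 1 (adjusted p = 0.0507), 0 h replicate 2 (0.0594) or 24 h replicate 1 (0.0650). Ctss, a lysosomal protease gene of macrophages, rose from 2.46 to 87.4 CPM (5.16 ± 0.68, adjusted p = 0.000494).

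At 48 h 2799 genes were called higher and 3387 lower, or 4415 and 2337 under library size alone. Oas2, an interferon-induced gene, was at least 100.1-fold higher (adjusted p = 0.00481), Oasl2 was at 21.8 CPM against 0.0696 CPM from 1 count at 0 h, and Ctss (6.24 ± 0.69, adjusted p = 0.000136) and Gatsl2 (5.43 ± 0.42) rose. Myo18b was at least 363-fold lower, Fxyd4 at least 208-fold and Trem3 at least 193-fold, and Mpo was at 0.0725 CPM from 1 count. Kit was at 0.489 ± 0.0754 CPM (-8.63 ± 0.49, adjusted p = 8.21e-06), Ly6c2 fell (-6.38 ± 0.23, adjusted p = 2.81e-06), and Cdkn1a rose (0.59 ± 0.18, adjusted p = 0.0228), but not without 0 h replicate 1 (0.56, adjusted p = 0.0924) or 48 h replicate 1 (0.43, 0.150).

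At 72 h 2876 genes were called higher and 3272 lower, or 4616 and 2228 under library size alone. Hoxa9 was at 230.0 ± 11.3 CPM against 140.0 ± 20.6 CPM at 0 h (0.72 ± 0.22, adjusted p = 0.0242), Meis1 rose by 1.10 ± 0.33 (adjusted p = 0.0213) and Pbx3 by 0.88 ± 0.14 (adjusted p = 0.000856), and Hoxa10 did not pass the test (0.50 ± 0.47, adjusted p = 0.388). The Hoxa9 call did not hold without 0 h replicate 1 (0.61, adjusted p = 0.126), 72 h replicate 1 (0.77, 0.0598) or 72 h replicate 2 (0.67, 0.0905), nor the Meis1 call without 0 h replicate 1 (0.84, 0.125) or 72 h replicate 1 (0.84, 0.119). Kit was at 0.188 CPM, from 3 counts, against 201 CPM. Myc was at 3.65 ± 2.80 CPM (-7.02 ± 0.80, adjusted p = 0.000161), and Cd34 (-1.88 ± 0.12), Cebpa (-1.98 ± 0.13), Myb (-1.40 ± 0.21) and Bcl2 (-1.41 ± 0.15) stayed lower. The largest rises with more than 3 counts at 0 h were in Ctss (5.85 ± 0.69, adjusted p = 0.000185), Gbp2 (5.18 ± 0.45), Gatsl2 (5.10 ± 0.42), the Fc receptor gene Fcgrt (4.86 ± 0.57), Gbp5 (4.56 ± 0.41), P2rx7 (4.27 ± 0.58) and Slc22a18 (4.03 ± 0.41). Besides Mpo and Ccnb2, the largest falls were in Myo18b, Bpifc, Mgam, Trem3 and Cldn15, at least 416-, 304-, 225-, 221- and 192-fold lower, and in Ngp, at 0.188 CPM from 3 counts against 708 CPM. Itgam was called lower (-0.35 ± 0.11, adjusted p = 0.0267), but its change was positive under library size scaling (0.02) and called higher under TPM (0.37, adjusted p = 0.0121).

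The MLL-fusion targets had more genes called higher than lower from 24 h on. Of 24 measured genes, 2, 8, 7 and 12 rose and 5, 3, 4 and 4 fell at 8, 24, 48 and 72 h (1, 8, 6 and 12 rose and 3, 3, 4 and 4 fell adjusted over the list alone), with medians of -0.04, 0.37, 0.47 and 0.70. The adjusted p was 0.881, 0.698, 0.680 and 0.585 with an estimated correlation, and the 8 h median was positive under library size (0.27) and TPM scaling (0.34). Without the 3 libraries high in Wnt2, 2 rose and 10 fell at 8 h (median -0.37) and 6 rose and 4 fell at 24 h (median 0.10). Of the stem and progenitor genes, 1, 2, 1 and 2 of 18 were higher and 7, 10, 10 and 10 lower (1, 3, 1 and 2 and 7, 10, 10 and 11 adjusted over the list alone) and medians of -0.79, -1.12, -1.45 and -1.30. The hematopoietic transcription factors had 0, 6, 5 and 5 of 28 higher and 18, 13, 12 and 15 lower (0, 7, 5 and 5 and 20, 14, 13 and 15 adjusted over the list alone), with medians of -1.07, -0.63, -0.72 and -0.68, the last 2 at 0.00 and 0.03 under TPM scaling. At 8 h Lyl1 (-1.99 ± 0.13) and Nfe2 (-1.87 ± 0.15) fell. The adjusted p was 0.327, 0.365, 0.321 and 0.327 for the stem and progenitor genes and 0.274, 0.346, 0.415 and 0.346 for the transcription factors, with an estimated correlation.

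Genes of the p53 pathway, cell death and stress responses went both ways. Of 25 p53 targets, 6, 12, 13 and 11 rose and 4, 2, 4 and 3 fell (6, 14, 13 and 11 and 4, 2, 4 and 3 adjusted over the list alone), with medians of 0.01, 0.59, 0.49 and 0.30. Ccng1 (0.82 ± 0.13) and Rrm2b (1.39 ± 0.22) rose and Perp fell (-1.32 ± 0.11, adjusted p = 9.27e-05) at 8 h, and Trp53inp1 rose at 24 h (2.18 ± 0.20). Of 12 BCL2-family genes, 0, 5, 4 and 4 rose and 5, 3, 3 and 3 fell (1, 5, 4 and 4 and 5, 3, 3 and 3 adjusted over the list alone), with medians of -0.16, 0.31, 0.43 and 0.37, with Bid (-1.74 ± 0.17) and Bmf (-2.14 ± 0.30) lower at 8 h and Mcl1 (1.01 ± 0.10) and Bcl2l11 (1.43 ± 0.16) higher at 72 h. At 8 h that list was called higher more often under library size scaling (4 higher, 3 lower) and under TPM (5 higher, 2 lower). The ATF4 and unfolded protein response genes had 1, 0, 1 and 1 of 29 higher and 15, 23, 23 and 18 lower (1, 0, 1 and 1 and 16, 25, 23 and 18 adjusted over the list alone), with medians of -0.70, -1.45, -1.39 and -1.13, and Atf4 fell at 8 h (-1.18 ± 0.15) while Atf5 rose at 72 h (2.29 ± 0.20). Of 28 immediate-early genes, 0, 2, 3 and 4 rose and 12, 9, 10 and 12 fell (0, 2, 3 and 4 and 15, 9, 10 and 12 adjusted over the list alone), with medians of -0.87, -0.33, -0.69 and -0.76 that were 0.06, 0.02 and 0.00 at 24, 48 and 72 h under TPM scaling, with Fosl1 (-4.14 ± 0.49) and Ier3 (-1.85 ± 0.32) lower at 8 h and Jun lower at 72 h (-4.09 ± 0.64). In the order of these 4 lists, the adjusted p at 8 h was 0.664, 0.452, 0.278 and 0.274 and at 72 h 0.346, 0.490, 0.287 and 0.424, with an estimated correlation.

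Monocyte, antigen-presentation, lysosome and respiration genes changed in part. Of 26 monocyte and macrophage genes, 1, 2, 2 and 1 rose and 14, 8, 8 and 10 fell (2, 2, 2 and 1 and 15, 6, 8 and 10 adjusted over the list alone), with medians of -1.85, -1.25, -0.91 and -1.87. Under library size alone 2 rose and 12 fell at 8 h, and 4 rose and 5 fell at 24 h (median -0.95). Adgre1 (-2.10 ± 0.16) and Ly6c2 (-1.51 ± 0.18) fell at 8 h. Of 13 antigen-presentation genes, 0, 0, 1 and 1 rose and 6, 4, 6 and 6 fell (0, 0, 1 and 1 and 6, 3, 6 and 6 adjusted over the list alone), with medians of -0.52, -0.28, -0.28 and -0.55 that were positive at 24 and 48 h under library size scaling (0.03 and 0.07) and at 24, 48 and 72 h under TPM (0.18, 0.34 and 0.08). Of 34 lysosome genes, 7, 12, 12 and 11 rose and 11, 9, 9 and 10 fell (7, 12, 12 and 11 and 12, 10, 10 and 10 adjusted over the list alone), with Lipa higher (1.56 ± 0.12) and Grn lower (-1.25 ± 0.10) at 8 h. Their medians of -0.19, 0.07, -0.06 and -0.17 were all positive under library size and TPM scaling, and at 48 and 72 h the mean and the list test were positive where the median was negative. Of 44 oxidative phosphorylation genes, 3 rose and 6 fell at 8 h and 31, 38 and 35 fell later (1 and 5, then 31, 39 and 36 adjusted over the list alone), with medians of -0.03, -0.51, -0.85 and -0.67, Cycs lower at 24 h (-1.59 ± 0.15), and adjusted p = 0.918, 0.336, 0.314 and 0.321 with an estimated correlation. Under library size alone 17 of them rose and 1 fell at 8 h, under TPM 27 rose and 0 fell, and with the trend on transcript length removed 11 rose and 5 fell. At 72 h the TPM median was 0.00, with 8 higher and 9 lower. For the monocyte, antigen-presentation and lysosome lists the adjusted p was 0.314, 0.490 and 0.452 at 8 h and 0.346, 0.606 and 0.785 at 72 h, with an estimated correlation.

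Chromatin genes included several that rose. Of 26 acetyltransferases and acetyl-lysine readers, 11, 11, 13 and 13 rose and 3, 4, 4 and 4 fell (13, 11, 13 and 14 and 3, 4, 4 and 4 adjusted over the list alone), with medians of 0.29, 0.26, 0.33 and 0.34 and adjusted p = 0.321, 0.336, 0.321 and 0.321 with an estimated correlation. Kat6b (1.18 ± 0.13) and Kat2b (1.12 ± 0.13) rose with Ep300 and Crebbp at 8 h. Under library size alone 18 genes of this list rose and 2 fell at 8 h. Of 22 deacetylases and sirtuins, 3 rose and 6 fell at 8 h and 6 rose and 3 fell at each later time (3 and 6 at 8 h, and 5, 6 and 5 and 3, 3 and 3 later, adjusted over the list alone), with medians of -0.04, 0.21, 0.08 and 0.13 and with Hdac7 (-2.16 ± 0.20) and Sirt3 (-2.12 ± 0.22) lower at 8 h. Under library size alone 7 of them rose and 4 fell at 8 h, and under TPM 9 rose and 2 fell. Of 31 MLL-complex and histone methylation genes, 7, 13, 17 and 15 rose and 3, 6, 7 and 6 fell (5, 13, 17 and 15 and 3, 6, 7 and 6 adjusted over the list alone), with medians of 0.15, 0.15, 0.36 and 0.31, of which the 24 h median was -0.06 with the trend on transcript length removed. Under library size alone 17 of these genes rose and 2 fell at 8 h, with a median of 0.46. Wdr5 (-1.29 ± 0.11, adjusted p = 9.87e-05) and Kdm6b (-1.39 ± 0.17) fell and Eed rose (1.04 ± 0.16) at 8 h, and at 72 h Ezh2 fell (-2.06 ± 0.15) and Ezh1 rose (1.76 ± 0.17). For the deacetylase and MLL-complex lists the adjusted p was 0.785 and 0.564 at 8 h and 0.585 and 0.377 at 72 h, with an estimated correlation.

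Among markers of other lineages, 5, 7, 8 and 8 of 11 mast-cell, basophil and eosinophil markers fell and 0 rose (5, 8, 8 and 9 adjusted over the list alone). Their medians were -2.46, -3.77, -4.25 (-4.18 with genes at 0 set to their bound) and -4.26, and Hdc (-2.13 ± 0.24) and Cpa3 (-2.39 ± 0.58) fell at 8 h. Of 6 megakaryocyte markers, 0, 1, 1 and 1 rose and 2, 3, 4 and 5 fell (0, 1, 1 and 1 and 2, 3, 5 and 5 adjusted over the list alone), with medians of -1.24, -2.86, -4.18 and -4.89, the last 2 at -4.02 and -3.99 with genes at 0 set to their bound. With an estimated correlation the adjusted p was 0.274 at each time for the first list and 0.327, 0.346, 0.321 and 0.321 for the second. Of 4 measured erythroid markers 0, 2, 2 and 3 fell and 0 rose. Of 4 T- and NK-cell markers 1, 2, 2 and 3 fell and 0, 0, 1 and 0 rose. Of 3 stromal markers 1, 1, 0 and 0 rose and 0 fell. No B-cell marker was measured, and these lists had no test. None of the 100 list tests passed with an estimated correlation in limma's camera (17 at an unadjusted p under 0.05), while 65 passed with a preset correlation of 0.01 and 76 with fry, which does not compare a list with other genes.

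Sets of genes at least 4-fold apart in the single libraries were followed in the time course. Of 253 measured genes higher in LSC than in GMP, 8 rose and 128 fell at 8 h (median -1.30, adjusted p = 0.0358 by camera with an estimated correlation), and 35 rose and 127 fell at 72 h (median -0.99, adjusted p = 0.149). The 8 h test of this set did not pass in 5 of the 10 fits with 1 library left out (adjusted p = 0.0525 to 0.0643). Of 197 genes lower in LSC than in GMP, 17 rose and 62 fell at 8 h (median -0.62, adjusted p = 0.0199) and 21 rose and 90 fell at 72 h (median -1.04, or -1.01 with genes at 0 set to their bound, adjusted p = 0.0199). Of 98 genes higher in LSC than in mAML, 2 rose and 66 fell at 8 h (median -1.72, adjusted p = 0.0394) and 3 rose and 76 fell at 72 h (median -2.17, adjusted p = 0.0483). At each of the 4 times this test did not pass in 7 of the 10 fits with 1 library left out. Of 389 genes lower in LSC than in mAML, 56 rose and 107 fell at 8 h and 99 rose and 122 fell at 72 h (adjusted p = 0.362 and 0.889). At 24 h 115 rose and 102 fell, and at 48 h 113 rose and 116 fell. At 24 and 48 h that last set had negative medians and means and a positive list test (adjusted p = 0.755 at both). Of the 16 set tests, 9 passed, 3 did without 24 h replicate 2, and 0 did with the sets built at 8-fold (9 at 8-fold under library size alone).

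Between 8 and 72 h, with no 0 h library in the comparison, 1675 genes were called higher and 1908 lower, or 1923 and 1736 under library size alone and 938 and 1123 without 72 h replicate 2. Clec7a (5.05 ± 1.45, adjusted p = 0.0275), Fcgrt (4.19 ± 0.53, adjusted p = 0.0007), Rgs11 (3.89 ± 0.77), Sap25 (3.88 ± 0.65), Ctss (3.29 ± 0.56) and Lppr3 (3.08 ± 0.67) were higher at 72 h. The Clec7a call was lost without 72 h replicate 1 (4.27, adjusted p = 0.0947) and without 8 h replicate 2 (4.05, 0.110), and that of Lppr3 without 8 h replicate 2 (2.58, 0.0502). Ccnb2 went from 209.6 CPM at 8 h to 0 counts, at least 1142-fold lower, and Mpo, E2f7, Fam64a, Mxd3 and Ankle1 were at least 1030.0-, 213-, 122-, 105- and 81.2-fold lower. The Mpo bound rests on the mean of 351 and 27.1 CPM in the 8 h libraries and would be lower from the second alone. Runx1 (2.51 ± 0.26), Itgam (1.48 ± 0.11) and Adgre1 (1.94 ± 0.16), which had fallen by 8 h, were higher at 72 h than at 8 h, as was Hoxa9 (0.80 ± 0.22, adjusted p = 0.0257; not called without 8 h replicate 1, 72 h replicate 1 or 72 h replicate 2, with 0.59, 0.85 and 0.75 and adjusted p = 0.130, 0.0661 and 0.110). All 50 G2/M genes and 43 of 45 S-phase genes were lower at 72 h than at 8 h, as were 33 of 40 ribosomal and 37 of 44 oxidative phosphorylation genes.

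Over the 4 treated times together, 6654 of 11119 genes were called by edgeR's test of any change. The same direction was called at all 4 times for 1308 genes higher and 1554 lower, or 2854 and 915 under library size alone. Independent lists of the same sizes would share 30.1 and 56.7 genes, and 20 simulations without an effect gave 0. With no effect few genes are called at any time, so these simulations cannot show how much shared 0 h libraries add. The 4 comparisons share the 0 h libraries, and no fit set different times against different 0 h libraries. Part of the excess may therefore come from these controls. Under library size alone the median change of all genes moved up by 0.31, 0.31, 0.35 and 0.37 at 8, 24, 48 and 72 h, and under TPM by 0.43, 0.50, 0.66 and 0.69, so directions above are relative to most genes being unchanged.

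**Figure D3:**
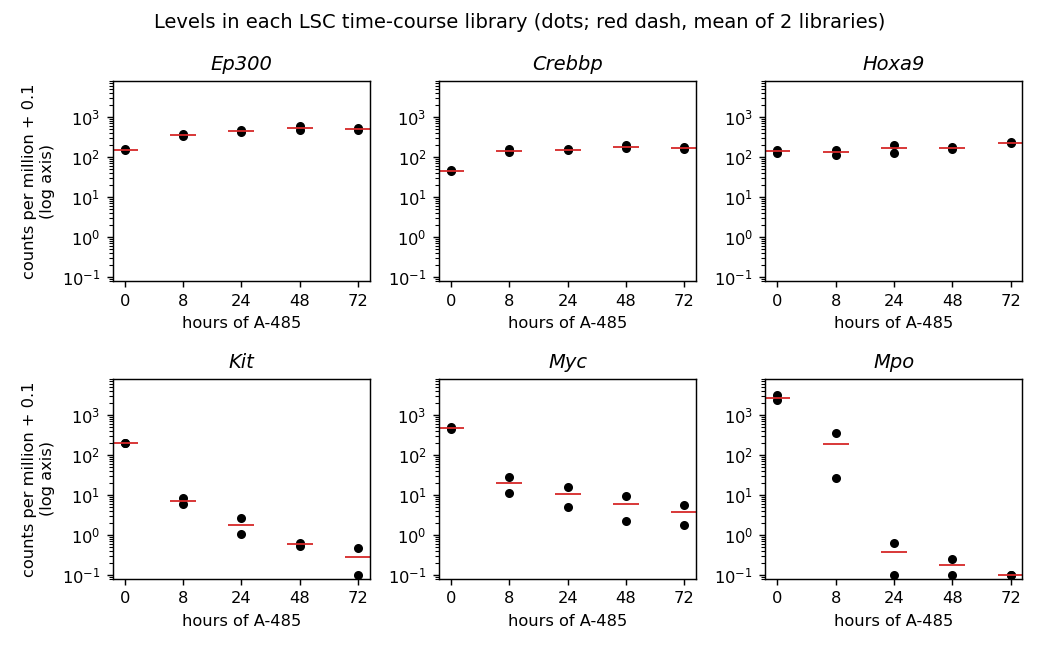
Levels of Ep300, Crebbp, Hoxa9, Kit, Myc and Mpo in each of the 10 time-course libraries, in CPM plus 0.1 on a log axis. Dots are libraries and the red dash is the mean of the 2. The change of Hoxa9 at 8 h, which did not pass the test, is positive under library size and TPM scaling.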

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

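The tests of the transcript length trend and both tests of the hypoxia and glycolysis genes were chosen only after the result was seen.

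The results here were picked out because the change at 8 h and the change at 72 h differed by edgeR's test of 72 h against 8 h. Of the genes called at both times, 49 were higher at 8 h and lower at 72 h, and 52 were lower at 8 h and higher at 72 h, each with the difference past the threshold. The genes named from these were chosen after their values were seen. Ckap2, a mitotic spindle gene, rose at 8 h (0.86 ± 0.29) and was lower at 72 h (-4.52 ± 0.39), a difference of -5.38 (adjusted p = 7.42e-05). Smc4, a condensin gene, went the same way, from 0.43 ± 0.12 to -1.01 ± 0.13, a difference of -1.44. Zfp36, which encodes an RNA decay factor, fell at 8 h (-0.98 ± 0.25) and was higher at 72 h (1.87 ± 0.24), a difference of 2.86. Bbc3, a BH3-only death gene, differed by 1.67, from -0.69 ± 0.23 to 0.99 ± 0.23, and Fosl2 by 1.43, from -0.53 ± 0.16 to 0.90 ± 0.16. The 8 h calls of all 5 genes were lost in some fits with 1 library left out. Bbc3 (-0.37, adjusted p = 0.211) and Fosl2 (-0.22, 0.270) lost theirs under library size alone, and both of these and Zfp36 under TPM (-0.20, -0.07 and -0.48). Ckap2 lost its 8 h call with the replicate block (0.85, adjusted p = 0.0621) and without the 3 libraries high in Wnt2 (0.47, 0.0957), and Smc4 its 72 h call under TPM (-0.29, 0.0865).

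Many members of some lists differed between these times by the same gene-level test, and no list test was run for 72 h against 8 h. At 72 h against 0 h the G2/M, S-phase, oxidative phosphorylation and ribosomal lists did not pass with an estimated correlation (adjusted p = 0.346, 0.274, 0.321 and 0.290). All 50 G2/M genes were lower at 72 h than at 8 h, as were 43 of 45 S-phase genes, 37 of 44 oxidative phosphorylation genes and 33 of 40 ribosomal protein genes. With 2 libraries per time and no vehicle at 72 h, a change with time in culture cannot be separated from a late effect of the drug.

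Ep300 and Crebbp rose at each treated time while longer transcripts rose as a class: the 2780 genes of lowest length had median changes of -0.13, -0.33, -0.48 and -0.39 at 8, 24, 48 and 72 h, and the 2780 genes of greatest length 0.16, 0.25, 0.32 and 0.29. A trend on transcript length between libraries could raise genes as long as these. With that trend removed, 8 of 8 tests stayed past the threshold and higher, with changes of 1.05 to 1.34 for Ep300 and 1.45 to 1.60 for Crebbp, so the length trend is not the whole cause. A response to the inhibitor may therefore be a candidate explanation, and a response to time in culture stays open, as untested.

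All 30 hypoxia and glycolysis genes were lower at 8 h than at 0 h. A candidate explanation is a raised level in the 0 h cultures: the 0 h libraries lay above the single LSC library by a list median of 1.74, in 29 of 30 genes, while the treated libraries lay at -0.30, -0.18, -0.23 and -0.28. Scaling of the libraries is argued against, since 29 members were still called lower at 8 h under library size alone. The single LSC library differs from the time course in depth and perhaps in handling. The 0 h values compared with it are those that picked this list, and no other list was compared with it. That comparison therefore cannot show a raised level particular to these genes, and a direct effect of A-485 on them stays open.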

How the results depend on the processing

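The fits without Rn45s, without the 3 libraries high in Wnt2 and with the trend on transcript length removed were chosen only after the result was seen; the rest were planned.

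Counts of called genes stayed within 1.5 times under DESeq2 size factors, the DESeq2 test, both low-count filters, the replicate block and the 3 added fits. They moved under library size alone and under limma on TPM. Under library size alone, genes higher were 4078, 4175, 4415 and 4616 at 8, 24, 48 and 72 h, genes lower at 8 h 1520, and all-4-times counts 2854 higher and 915 lower. Under limma on log2(TPM + 1), genes higher were 4859, 5105, 5808 and 6104 and genes lower 1358, 1600, 1743 and 1638; for 72 h against 8 h they were 3217 and 1240, and for all 4 times 3731 and 725. Both scalings let the median of all genes move up, which by construction raises the count of genes higher. The limma fit also changed the test and scaled for length, so its counts cannot be put down to library scaling alone. With only the 4 libraries compared, 1060 genes were higher at 72 h than at 8 h; the cause was not tested.

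With 1 library left out, where the lone library of that time is assumed to vary like the others, counts at 8 h ranged from 1186 (without 8 h replicate 2) to 2128 higher and from 1496 (without 0 h replicate 2) to 2481 lower. Without 0 h replicate 1 they were 1275 and 1517, and without 0 h replicate 2 1220 were higher. At 24 h the ranges were 1796 to 2690 and 2017 to 3044, at 48 h 1991 to 2893 and 2488 to 3514, and at 72 h 2226 to 2979 and 2472 to 3408. For 72 h against 8 h they were 938 to 1753 and 1123 to 2006, both lowest without 72 h replicate 2. Any time gave 4895 to 6997. All 4 times gave 849 to 1268 higher and 947 to 1506 lower, with 849 and 963 without 0 h replicate 2 and 859 and 947 without 0 h replicate 1. List tests stayed at 0, and the 9 LSC set tests ranged from 3 (without 24 h replicate 2) to 9, with 4 without 0 h replicate 1, 24 h replicate 1 or either 48 h library and 5 without either 72 h library. The cause was not tested.

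Camera with a preset correlation of 0.01 passed 65 list tests and fry 76, against 0 with the estimated correlation. At 72 h the estimated correlation was 0.80 for the G2/M, 0.72 for the neutrophil maturation and 0.50 for the ribosomal list. A value above the preset makes the test of a list stricter. The lysosome list had 0.02 and the megakaryocyte list -0.04. Fry does not compare a list with other genes. How much each of these accounts for was not tested. With LSC sets built at 8-fold 0 of 16 tests passed (9 at an unadjusted p under 0.05; 12 with the preset correlation and 14 with fry). At 8-fold with the estimated correlation, 9 passed under library size alone, 3 with the replicate block, 4 without 0 h replicate 2 and 0 in each of the other 9 fits with 1 library left out. The cause was not tested. With a minimum of 1 CPM in place of 10, the single libraries gave 622 higher and 678 lower for LSC against GMP, 1072 and 241 for mAML against LSC, and 1416 and 595 for mAML against GMP. With 50 CPM these were 151 and 54, 290 and 47, and 484 and 78, since the minimum sets the number of genes considered.

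Of 168 named gene results in the time course, 143 never lost their call or reversed. Results without a call, such as Hoxa10 at 8 h, are among the 168 and had none to lose. In the next counts, a call kept includes a result called in neither fit. The fit without Rn45s left all 168 the same. These shares therefore do not measure the firmness of the calls alone. Over 3525 comparisons, 3416 kept direction and call, 89 lost the call (66 with 1 library left out), 9 gained it and 11 changed direction (4 with 1 library left out). Hoxa10 at 8 h was 0.26 under library size alone, 0.34 under TPM, 0.20 without 0 h replicate 2, 0.44 without 8 h replicate 1 and 0.0175 with the length trend removed, and with 1 library left out it ranged from -0.76 (without 8 h replicate 2) to 0.44. Hoxa9 at 8 h was 0.23, 0.35, 0.12 and 0.13 under the first 4 of these, and ranged from -0.30 (without 8 h replicate 2) to 0.13. Itgam at 72 h was 0.0183 under library size alone and 0.37 under TPM. The cause was not tested.

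Beside those given in the report, calls lost with 1 library left out included Itgam at 72 h (-0.21, 0.236, without 0 h replicate 1), Cpa3 at 8 h (-1.90, 0.0790, without 0 h replicate 1), and Oasl2 at 48 h (adjusted p = 0.0681 and 0.0510 without either 0 h library). Bbc3, Ckap2, Fosl2, Smc4 and Zfp36 at 8 h lost their call without at least 2 of the libraries, in turn: without 0 h replicate 2 Bbc3 was at -0.24 and Fosl2 at -0.28, without 8 h replicate 2 Ckap2 at 0.47 and Smc4 at 0.30, and without 0 h replicate 1 Zfp36 at -0.61. Cxcl10 at 8 h lost its call in each fit with 1 library left out (adjusted p = 0.0520 to 0.525) except the fit without 8 h replicate 1, and Rsad2 lost its call without either 0 h library (adjusted p = 0.122 and 0.0997). Under TPM Bbc3 (-0.20), Fosl2 (-0.07) and Zfp36 (-0.48) at 8 h were not called either, nor was Bcl2 (-0.45) at 8 h.

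The labels do not say whether replicate numbers pair the libraries, so the block is an alternative only. Correlations of the replicate differences between times ranged from -0.41 to 0.64 over 10 pairs, with 3 above 0.1. The value of 0.64 was between 8 and 24 h, and 72 h had -0.40 with 8 h and -0.41 with 24 h, which follows the replicate numbers of the 3 libraries high in Wnt2. With the replicate block, genes higher and lower were 1902 and 2295 at 8 h and 2822 and 3220 at 72 h. With the replicate block Ckap2 at 8 h lost its call (0.85, adjusted p = 0.0621). Depth limits genes with few counts, such as Cd28 or Ngp. In simulated data of the same depth and number of libraries 39% to 52% of 2-fold changes against 0 h were recovered, and depth was not varied. The simulated data had far fewer changed genes than were called here.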

Other observations

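The tests of stromal markers and of library labels were chosen only after the result was seen.

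By 72 h of A-485 all 14 primary granule genes and 14 of 16 neutrophil maturation genes were lower, and of 26 monocyte and macrophage genes 1 was higher and 10 lower. None of these lists passed its test at 72 h with an estimated correlation (adjusted p = 0.274, 0.452 and 0.346). Ctss (5.85 ± 0.69), Fcgrt (4.86 ± 0.57) and Gbp2 (5.18 ± 0.45) rose. They were picked by the size of their rise and do not stand for macrophage genes as a group. Of 98 genes higher in LSC than in mAML 76 fell, and of 389 genes lower in LSC than in mAML 99 rose and 122 fell. The test of the first set was near the threshold (adjusted p = 0.0483): it was lost in 7 of the 10 fits with 1 library left out (0.0525 without 0 h replicate 1, 0.0831 and 0.0733 without 24 h replicates 1 and 2, 0.0745 and 0.0744 without 48 h replicates 1 and 2, and 0.0754 and 0.0720 without 72 h replicates 1 and 2) and with the set built at 8-fold (0.0758). The mAML library also carried T- and NK-cell markers, some erythroid markers and the B-cell gene Cd22. The second set is therefore not a measure of myeloid maturation alone. Of 14 B-cell markers 4, and of 18 erythroid markers 8, reached 1 CPM in mAML or LSC.

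By 72 h 3 genes tied to MLL fusions were higher while Kit and Myc were low, and the list as a whole was mixed. Kit was at 0.188 CPM at 72 h, from 3 counts, and Myc at 3.65 CPM, while Hoxa9 (0.72 ± 0.22), Meis1 (1.10 ± 0.33) and Pbx3 (0.88 ± 0.14) were higher than at 0 h. Hoxa10 did not pass the test (0.50 ± 0.47, adjusted p = 0.388). Of 24 MLL-fusion targets 12 were higher, 4 lower and 8 not called, with a list adjusted p = 0.585 with an estimated correlation. The Hoxa9 and Meis1 calls were lost without 0 h replicate 1 (0.61 and 0.84) and without 72 h replicate 1 (0.77 and 0.84), and that of Hoxa9 also without 72 h replicate 2 (0.67).

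A group of 3 treated libraries, 8 h replicate 2, 24 h replicate 2 and 72 h replicate 1, shared high levels of genes that were chosen after their values were seen. Wnt2 was at 67.1, 69.2 and 20.9 CPM, Susd5 at 65.6, 76.1 and 33.4 CPM and Foxc1 at 223, 306 and 141 CPM, against at most 3.58, 2.51 and 42.3 CPM in the other 7 libraries. Stromal or endothelial cells could be a source. Yet the summed stromal and endothelial markers, without TMM scaling, reached 10.6 CPM in the highest of the 3 libraries. They reached 14.7 CPM in the highest of the others, which argues against this source. For 8 h replicate 2 and 72 h replicate 1 a swap of labels between times is argued against. Each correlated best with the other library of its time (Spearman 0.974 and 0.985). For 24 h replicate 2 a swap is not settled. This library correlated better with 72 h replicate 1 (0.981) than with 24 h replicate 1 (0.971). Libraries without the high Wnt2 did the same. The best match of 24 h replicate 1 was 48 h replicate 2 (0.979). Replicate 2 of 48 h and replicate 2 of 72 h matched each other best (0.993). A best match at another time therefore does not by itself mark a swap. Its G2/M sum of 2058 CPM lay outside the range of every other time, but each range rests on 2 libraries. The other 24 h library was at 3851 CPM. A difference in culture or in the cells of these libraries stays open, as untested.

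Ribosomal RNA from Rn45s made up 0.133% of counts in GMP and up to 1.02% in 0 h replicate 1. Replicate pairs differed by more than counting noise, with a chi-square per degree of freedom of 10.9, 21.6, 24.1, 5.80 and 13.9 at 0, 8, 24, 48 and 72 h, so no pair is the same library read again. In a principal component analysis of the time course the first 2 components held 59.3% and 19.4% of the variance. On the second, 8 h replicate 2, 24 h replicate 2 and 72 h replicate 1 were at -70.6, -31.7 and -0.499. The other libraries of these times were at -33.3, 3.17 and 23.4. So the 3 libraries high in Wnt2 each lay below the other library of their time. The pairs at 0 and 48 h lay closer, at 29.2 and 30.8 and at 28.1 and 21.4.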
